A study of Mus musculus with 8 samples.

How the data were processed

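The series holds 8 libraries of mouse bone marrow cells: fresh lineage-depleted marrow and 2-week M3434 cultures with DMSO, SB204990 or CB-839, each with 1 RNA and 1 ATAC library. The protocol in the labels gives 30 uM for SB204990 and no dose for CB-839, which the titles write as CB-389 and the descriptions as CB839; it is read here as CB-839. The labels call the cells lineage-negative and c-Kit-positive, while the protocol names lineage depletion and a viability sort only.

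The deposited RNA matrices hold raw UMI counts per gene and cell, with barcodes already restricted to called cells. The deposited ATAC matrices hold counts of cut sites per peak and cell and, in a second table, per motif and cell; peaks were called per library by the authors. Between 89.3% and 92.7% of ATAC entries are even, since most fragments add both ends, so ATAC intervals rest on counts divided by 2. Deposited peak coordinates start from 0. Per the submitters' processing notes, Cell Ranger 3.0.2, Cell Ranger ATAC 1.2.0 and ArchR 1.0.0 were used with build mm10. Per the file headers, the RNA matrices were written by software version 3.1.0 and the ATAC matrices by 1.2.0. ArchR output was not used here.

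RNA depth was 18113164 UMIs in 686 barcodes (fresh), 42898910 in 2867 (DMSO), 81637891 in 4383 (SB204990) and 51892838 in 3485 (CB-839). Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library in scanpy at an expected 0.8% per 1000 barcodes, called 6 of 11421 barcodes (0.053%), so doublets were in effect not removed. The 10621 cells kept had medians of 26869 (fresh), 12714 (DMSO), 18990.5 (SB204990) and 11748.5 (CB-839) UMIs. Counts were scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (seed 20), without integration. Of 25 clusters, 18 were named from 14 marker lists when the best list led by 0.6 (log2) and at least 3 markers were detected. A cluster also stayed unnamed when its 10 leading genes held more markers of another list, when it had few UMIs and no leading marker of its own, or when Ccl17, Ccl24, Mgl2 or Retnla was among the leading genes of a neutrophil cluster, which left cluster 7 unnamed. These naming limits were set after the clusters were seen. The groups, comparisons, filters, gene and marker lists, motif families and the rule for named genes were set before the data were examined.

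UMIs were summed per library or class, and log2 ratios of UMIs scaled to an equal total (CPM) carry exact conditional binomial 95% intervals. Classes with at least 100 cells in both libraries were compared. Genes named over all cells are the 10 highest and 10 lowest with at least 200 UMIs over both libraries and 30 CPM in one, and within classes the 3 highest and 3 lowest. They leave out ribosomal, mitochondrial, Gm and Rik genes, antigen receptor segments and sex-linked genes. Of each list up to 4 members with the widest ratios, Acly and the markers of classes may be named too, while some genes the rule picks are not reported here; for DMSO over fresh and SB204990 over CB-839 only some of the named genes are printed. List medians use members of at least 10 CPM, a pseudocount of 1 CPM and 10000 random lists matched in 20 expression bins; their ranges come from 200 Poisson redraws. Shares carry Clopper-Pearson intervals. Of 21 gene lists and 14 marker lists, T and NK and stromal and endothelial markers had under 3 measured members over all cells and have no median. For the same reason B lineage markers have none for either inhibitor over DMSO.

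ATAC depth was 304726536 cut sites in 6484 cells (fresh), 114484105 in 4478 (DMSO), 187856301 in 8876 (SB204990) and 125519144 in 3244 (CB-839). Overlapping peaks of 2 libraries were merged, and regions with a peak in both were compared after scaling to their total. Peak overlaps were found with bedtools. Gene spans come from a mm10 gene table without strand, so no promoters were defined. All 503 list genes matched the table. Regions named had at least 200 cut sites and peak lengths within 1.5 times. Motif ratios compare shares of the motif table; 93 of 102 motifs listed for 17 families are among its 579 motifs.

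The gene statistics were tested on simulated data with 200 changed genes. The simulated library sums were Poisson draws, the error that the intervals assume. The values below therefore check the calculation and not the spread of real UMIs between cells. This test was written after the real ratios had first been computed, and runs ahead of them in the final order. For SB204990 over DMSO (7538 genes), 67 of 67 genes at 1.5-fold, 67 of 67 at 2-fold and 66 of 66 at 4-fold were recovered, and intervals held the true value for 95.1% of unchanged genes; simulated CB-839 over DMSO gave the same counts. A simulated list set 2-fold higher gave a median of 0.94 for SB204990. An unchanged list of 20 genes lay at percentile 97.3 there and at 58.9 for simulated CB-839 over DMSO, with 1 such list each. A percentile alone therefore shows little when few genes differ. Random lists draw genes independently, which members of a real list need not be. For simulated pairs of cut sites, intervals held the truth for 96.0% of regions.

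Alternatives were other cell filters, doublets kept, marker scores per cell, TMM and DESeq2 scaling, mean CPM per cell, class weights of the reference library, a pseudocount of 10 CPM, no low-value filter, thinning to 2000 UMIs per cell, reciprocal overlap of 50%, only the peaks with more counts, and 3 other motif scalings. After the data were seen, 4 more were added: every cluster named after its best marker list, leaving out the highest doublet scores, cells of at least 5000 UMIs, and ATAC regions of like peak length. Software was Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, bedtools 2.31.1, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0. No p-values were computed from cells, since cells of 1 library are not replicates.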

Results

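Lineage-depleted bone marrow cells of C57BL/6 mice were compared fresh and after 2 weeks in M3434 methylcellulose with DMSO, SB204990 (an inhibitor of ATP citrate lyase, ACLY) or CB-839. The question addressed is how either inhibitor bears on the cells that grow from marrow progenitors. Each group has 1 RNA library and 1 ATAC library, so no difference below could be set against a spread between replicates. No significance test between groups was run. Intervals in parentheses are 95% intervals that cover counting error only.

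The 4 RNA libraries held different cell classes, named here after the marker list that led in each cluster. Fresh marrow had 46.0% (42.1 to 49.9%) neutrophil progenitor-like, 15.9% erythroid-like and 14.8% megakaryocyte-like cells, and 0 of its 655 cells were mast-like. These fresh shares depend on the clustering: erythroid-like cells were 8.02% without a filter and 27.0% under the stricter one, which named 0 megakaryocyte-like cells, and neutrophil progenitor-like cells 64.3% without a filter and 23.2% by marker score. In the DMSO culture 58.2% (56.4 to 60.1%) of 2740 cells were mast-like, 8.94% basophil-like, 3.36% macrophage-like and 1.57% erythroid-like. In the SB204990 culture 20.1% (18.9 to 21.4%) of 3984 cells were mast-like and 29.3% (27.9 to 30.8%) macrophage-like. In the CB-839 culture 45.8% (44.1 to 47.6%) of 3242 cells were mast-like, 14.4% basophil-like and 8.21% macrophage-like. The mast-like share of SB204990 lay -38.1 percentage points (-40.3 to -35.9) from that of DMSO, and that of CB-839 -12.4 points (-14.9 to -9.86). The macrophage-like share was 26.0 points (24.4 to 27.6) higher with SB204990 and 4.85 points (3.66 to 6.03) higher with CB-839. Without a filter on cells the macrophage-like difference of SB204990 was 13.09 points, and 50.4% of its cells were unnamed. Of the CB-839 mast-like cells 738 lay in cluster 15, whose cells had a median of 2110 UMIs. With only cells of at least 5000 UMIs the mast-like difference of CB-839 was -22.55 points, and with at least 1000 genes and at most 5% mitochondrial UMIs -21.28. With each cell given its highest marker score the macrophage-like difference of CB-839 was 1.44 points.

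**Figure D1:**
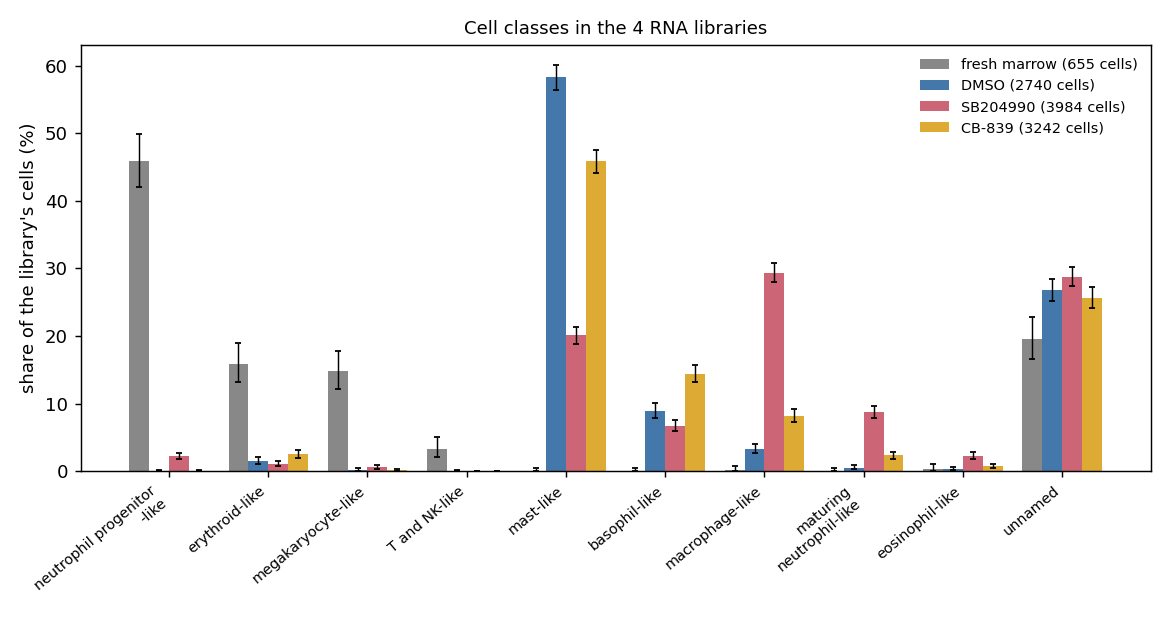
Share of each RNA library's cells (%) in each named class and in the unnamed clusters, as bars from 0 with 95% Clopper-Pearson intervals that cover counting of cells only. Mast-like cells make up 58.2% of DMSO, 20.1% of SB204990 and 45.8% of CB-839 cells.

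Maturing neutrophil-like cells made up 8.79% of the SB204990 library, 2.34% of CB-839 and 0.547% of DMSO, a difference of 8.24 points between SB204990 and DMSO. That difference rests on leaving cluster 7 unnamed: with every cluster named after its best marker list the shares were 12.07% of SB204990, 12.99% of CB-839 and 11.97% of DMSO, so no difference between SB204990 and DMSO is claimed. It also depends on the clustering: with the 6 called doublets kept the class held 166 SB204990 and 165 DMSO cells instead of 350 and 15, a difference of -1.86 points. Between 19.5% (fresh) and 28.8% (SB204990) of cells stayed unnamed. Cluster 7, with Ccl24, Car4 and Ccl17 among its leading genes and neutrophil markers as its best list, held 11.4% of DMSO, 3.29% of SB204990 and 10.6% of CB-839 cells. Cluster 11 (Akr1c18, Slc6a4 and Hdc leading, basophil markers as best list) held 15.1% of SB204990, 1.57% of DMSO and 2.50% of CB-839 cells. With every cluster named, basophil-like cells made up 25.7% of SB204990, 11.6% of DMSO and 19.1% of CB-839, against 6.70%, 8.94% and 14.4% as named here. Cluster 14 (Gzma, Gzmb and Eomes leading, mast markers as best list) held 12.4% of DMSO, 0.301% of SB204990 and 9.22% of CB-839 cells.

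Over all cells the genes with the highest SB204990 to DMSO ratios were Mpo (log2 ratio 4.97, 4.82 to 5.12, 271 against 8.65 CPM, UMIs scaled to an equal library total), Prtn3 (4.76), Wfdc17 (4.25), Pmp22 (4.10), Pltp (4.01), Npy (3.82), Gpnmb (3.73), Ms4a6c (3.61), Ms4a7 (3.57) and Elane (3.54). The lowest were Gzma (-14.60, 4 UMIs against 52352), Car4 (1 UMI against 11300, with an interval of -19.69 to -11.91), Ccl24 (-8.57), Tnfrsf9 (-6.84), Ccl17 (-6.84), Igfbp5 (-6.76), Hba-a2 (-6.52), Eomes (-5.86), Chil3 (-5.55) and Pga5 (-5.44). For CB-839 over DMSO the ratios were smaller. The highest were Cck (2.89), Ly6g (2.77), Retnla (2.67), Camp (2.50), Retnlg (2.44), Rbp4 (2.26), Arg1 (2.25), Mpo (2.18), Ngp (1.97) and Mrc1 (1.88), and the lowest Isg15 (-2.36), Rtp4 (-2.33), Mcpt1 (-2.31), Oasl2 (-2.25), Cxcl3 (-2.15), Gzma (-2.14), Fosb (-2.09), Tpsab1 (-2.08), Fos (-2.05) and Ccl5 (-1.90). Acly, the target of SB204990, stood at 46.4 CPM with DMSO, 58.3 with SB204990 and 54.9 with CB-839.

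Marker lists were compared over all cells. The median log2 ratio of SB204990 over DMSO was -2.48 for mast, -1.26 for basophil, -3.52 for erythroid, 2.36 for macrophage, 2.84 for neutrophil progenitor, 1.72 for maturing neutrophil, 1.09 for monocyte, -1.07 for stem and multipotent progenitor, 0.36 for dendritic, 0.51 for eosinophil and 0.87 for megakaryocyte markers. For CB-839 over DMSO it was -0.86, -0.44, 0.67, 0.44, 1.5, 1.29, 0.12, -0.19, 0.66, 0.31 and -0.19 for the same lists. With DMSO class weights, which cover only classes and clusters with at least 20 cells in both libraries (79.5% of SB204990 and 86.2% of DMSO cells, and 95.5% of CB-839 and 98.6% of DMSO cells), the SB204990 mast median was -0.58 and the macrophage median 0.20. The SB204990 monocyte, dendritic, eosinophil and megakaryocyte medians became -0.55, -1.60, -0.084 and -0.27, the CB-839 eosinophil median -0.28, and the CB-839 macrophage and erythroid medians -0.043 and -0.005.

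Immediate early genes had a median log2 ratio of -1.27 with SB204990 and -1.34 with CB-839, both below all 10000 matched random lists (percentile 0). With SB204990, Fosb was at -3.59, Egr1 at -3.27 and Ier2 at -2.27, while Atf3 lay at 2.28. With CB-839, Fosb was at -2.09, Fos at -2.05, Jun at -1.59 and Ier2 at -1.57. Interferon response genes had medians of -1.29 and -1.04, with Isg15 at -2.24 and -2.36. Inflammatory cytokines and chemokines had medians of -1.12 and -0.72. DMSO itself lay above fresh marrow for these lists, by 2.36 for immediate early genes, 2.51 for interferon response and 3.68 for inflammatory genes. SB204990 over CB-839 gave -0.05 for immediate early genes. TMM and DESeq2 scaling moved the median of all genes by 0.11 and 0.13 for SB204990 over DMSO, by 0.08 and 0.10 for CB-839 over DMSO and by 0.27 and 0.25 for DMSO over fresh.

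Among the metabolic lists over all cells, SB204990 over DMSO gave medians of 0.61 for glycolysis (percentile 100, Pgam1 1.16, Pgk1 1.01, Pkm 0.84), 0.56 for NRF2 targets (Hmox1 1.65), 0.31 for SREBP2 targets (percentile 99.95), 0.25 for the citric acid cycle, 0.24 for the respiratory chain, 0.12 for fatty acid synthesis, -0.20 for histone acetylation and acetyl-CoA supply, -0.35 for glutamine use and transport (Glul -2.04, Slc7a5 -1.31) and -0.40 for ATF4 targets. The LXR median was 0.09 with a mean of 1.10, since Pltp (4.01), Apoe (2.77) and Lpl (2.35) lay far above the other members. CB-839 over DMSO gave 0.36 for glycolysis (percentile 100), 0.15 for NRF2 targets, -0.02 for SREBP2 targets, 0.11 for both the citric acid cycle and the respiratory chain, -0.01 for fatty acid synthesis and -0.13 for histone acetylation. Glutamine use and transport lay at -0.11 (percentile 29.8, Glul -0.89), ATF4 targets at -0.04 and LXR targets at -0.02 (mean 0.06). Of the remaining lists, lysosome and granule enzymes lay at 1.13 with SB204990 (Ctsb 3.01, Lyz2 2.85) and 0.06 with CB-839, and G2 and M phase genes at 0.58 and 0.56. S phase genes lay at 0.19 and 0.21, integrins at 0.51 and 0.36, lineage transcription factors at -0.25 (mean 0.15) and -0.38, heat shock genes at 0.02 and 0.15, p53 targets at -0.26 and -0.19, and red cell genes at -3.43 and 0.44. With classes weighted as in DMSO the SB204990 integrin median was -0.10 and the CB-839 red cell median -0.21. The other lists here are given without such weights, so their medians mix class shares with differences within classes. Macrophage-like cells were 29.3% of SB204990 and 3.36% of DMSO cells. Some SB204990 medians had opposite signs in mast-like and basophil-like cells, such as glycolysis (0.497 and -0.256) and SREBP2 targets (0.272 and -0.222).

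**Figure D2:**
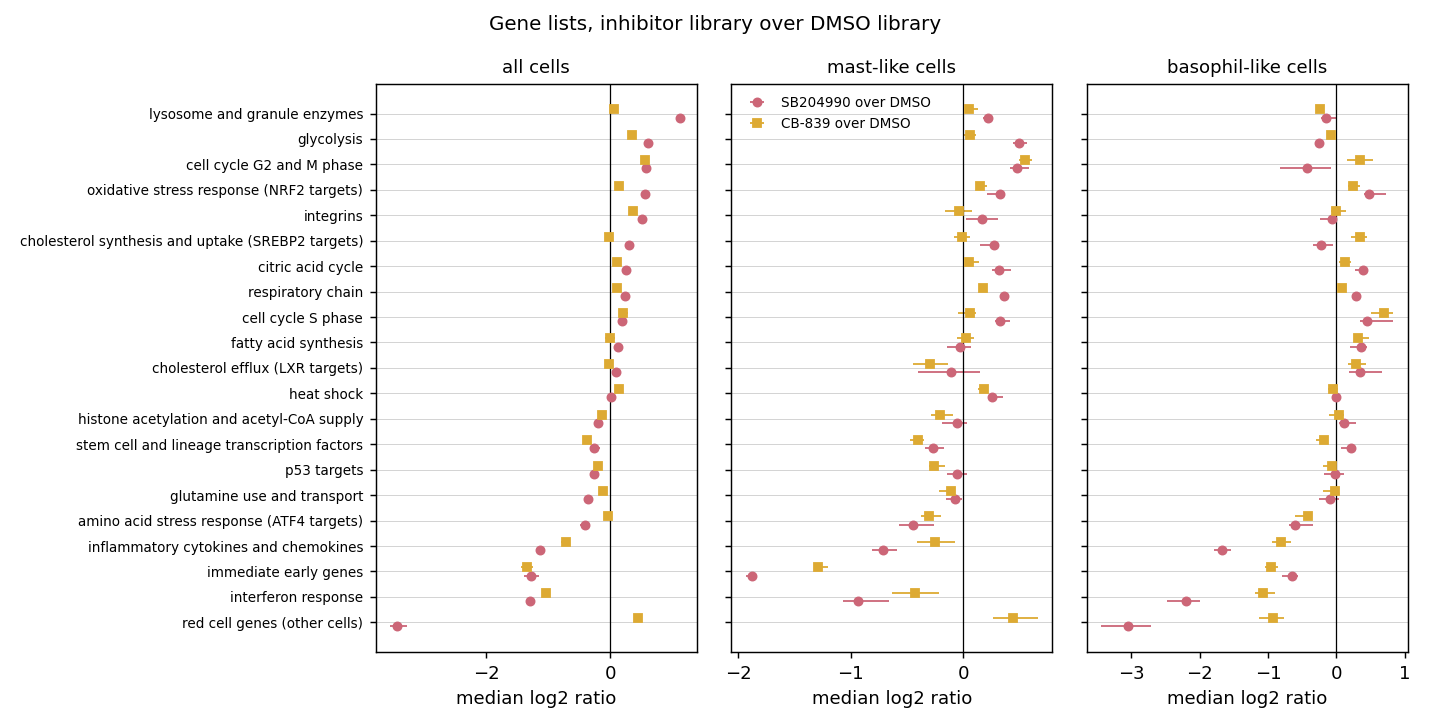
Median log2 ratio of each gene list, SB204990 (circles) and CB-839 (squares) over DMSO, over all cells, in mast-like and in basophil-like cells, with the 95% range of Poisson redraws of the counts. Immediate early genes lie at -1.27 and -1.34 over all cells.

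Within mast-like cells the immediate early median was -1.88 with SB204990 (802 against 1596 cells) and -1.29 with CB-839 (1486 cells), and the interferon median -0.94 and -0.43. The mast-like cells came from different clusters: mainly cluster 13 in DMSO (717 cells), clusters 17 and 15 in SB204990 (334 and 306) and clusters 15 and 16 in CB-839 (738 and 454), and a cluster mostly of 1 library may differ for that reason alone. In cluster 12, which all 3 cultures share, the immediate early median was -1.49 with SB204990 (99 against 140 cells) and -1.59 with CB-839 (118 cells). In cluster 15 (306 SB204990, 738 CB-839 and 321 DMSO cells) it was -0.84 and -1.16, with interferon medians of -1.42 and -0.45. Btg2 was among the lowest genes of mast-like cells with both inhibitors (-3.49 and -3.47), beside Igfbp5 (-4.12) and Hist2h2aa1 (-3.35) for SB204990 and Vill (-2.26) and Erv3 (-2.22) for CB-839. Mcpt8 (2.75), Calca (2.68) and Hbb-bt (2.33) were highest with CB-839, but Hbb-bt UMIs were in 6.39% of its mast-like cells (median 4352 UMIs), 6.02% of its macrophage-like cells (median 21174.5 UMIs) and 21.4% of its basophil-like cells (median 23405 UMIs), and Hbb-bt is not read as a change of mast-like cells. Prg2 (5.97), Lyz2 (4.56) and Ngp (4.23) were highest with SB204990, but Ngp UMIs were also in 65.9% of erythroid-like cells of that library (median 38783 UMIs) against 56.2% of its mast-like cells (median 6369.5 UMIs). Prg2 UMIs were in 47.7% of erythroid-like and 32.8% of mast-like cells, and Lyz2 UMIs in 52.3% and 35.4%, and none of the 3 genes is read as a change of mast-like cells.

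Basophil-like cells leave out cluster 11 (603 SB204990, 43 DMSO and 81 CB-839 cells), so the values that follow cover a minority of the SB204990 cells with basophil markers, and under the stricter filter only 17 SB204990 cells had that name. Within basophil-like cells (245 DMSO, 267 SB204990 and 468 CB-839 cells) the interferon median was -2.20 with SB204990 and -1.07 with CB-839, and the immediate early median -0.64 and -0.96. SB204990 cells lay mainly in cluster 21 (248) and DMSO and CB-839 cells in cluster 10 (219 and 426). Tnfrsf9 was at -8.12 with SB204990, while Penk and Xcl1 were listed at 0 UMIs against 843 and 713 in DMSO. Tnfrsf9 and Penk are among the leading genes of cluster 10, so their ratios in part restate that cluster split. Lyz2 (6.57), Ngp (4.36) and Ramp1 (3.99) were highest with SB204990, but Ngp UMIs were in 68.5% and Lyz2 UMIs in 59.2% of these cells (median 19510 UMIs), near the shares in erythroid-like cells, and neither is read as a change of basophil-like cells. With CB-839, Ly6g (3.66), Fat3 (2.31) and Hk3 (2.15) were highest and Xcl1 (-5.28), Igfbp5 (-4.16) and Csf2 (-3.38) lowest.

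The 2 inhibitors' log2 ratios to the 1 DMSO library had a correlation of 0.551 and a covariance of 0.161 across 8028 genes, which are not independent replicates. Unchanged libraries simulated against the same DMSO library gave a correlation of 0.598 and a covariance of 0.0018. These hold counting noise only, so their correlation is no yardstick for libraries that differ by more. Their covariance lay far below the observed one. A state of the DMSO library itself is in every one of these values and was not separated. With DMSO cells split at random so that SB204990 and CB-839 had separate references, the covariance was 0.153 and the correlation 0.508. Within mast-like cells the covariance was 0.083 (0.077 with split DMSO cells, 0.0043 simulated), and within basophil-like cells 0.088 (0.047 and 0.0147). The correlation in basophil-like cells was 0.315, and 0.157 with split DMSO cells.

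SB204990 over CB-839 set the inhibitor cultures directly against each other. Over all cells C1qc (5.24), C1qb (5.09), Apoe (3.99) and Gpx3 (3.79) were highest and Gzma (-12.46), Ccl24 (-9.51), Tnfrsf9 (-7.49) and Ccl17 (-7.14) lowest, with Car4 at 1 UMI against 10001. The macrophage median was 1.77, lysosome 1.11, mast -1.48 and erythroid -3.14. In macrophage-like cells (1169 SB204990, of which 1023 in cluster 22, and 266 CB-839, of which 226 in cluster 6), Cxcl10 was at 39.2 against 0.32 CPM and C1qa at 52.3 against 2.90. Chil3 was at 99.6 against 30224 CPM, Arg1 at 5.09 against 979, and Car4 at 0 UMIs against 227. Chil3 and Arg1 are among the leading genes of cluster 6, so their ratios in part restate that cluster split. The interferon median of these macrophage-like cells was 2.10. The 92 macrophage-like DMSO cells (57 in cluster 6, 19 in cluster 8 and 16 in cluster 22) had 0 Cxcl10 UMIs. They lay nearer to SB204990 for C1qa (67.0 CPM) and on a log scale nearer to CB-839 for Chil3 (12081 CPM) and Arg1 (525 CPM).

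**Figure D3:**
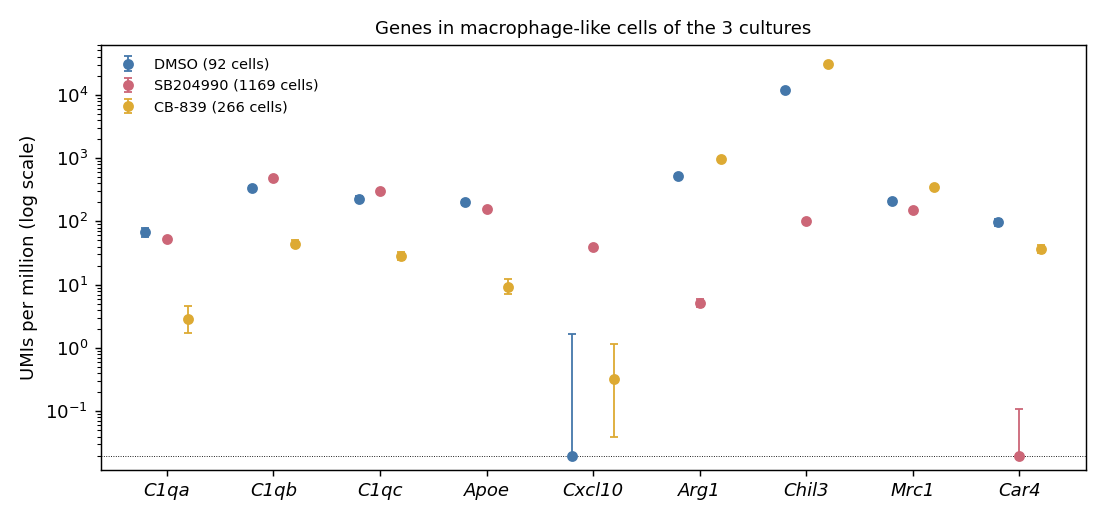
CPM (log axis) in the macrophage-like cells of the 3 cultures, with 95% Poisson intervals; points on the dotted line had 0 UMIs. Chil3 lies at 99.6 with SB204990 and 30224 with CB-839.

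DMSO culture over fresh marrow gave the widest ratios. The fresh library was lineage-depleted, while the culture grew for 2 weeks after that depletion. For markers of mature cells the depletion and the culture cannot be told apart. Tpsb2, Tph1, Tpsg1, BC100530 and Mmp12 had 0 UMIs in fresh marrow against 423334, 129641, 44631, 38963 and 14471 with DMSO, and Cma1 had 10 against 353851. Ly86, Mzb1, Dntt, Ly6d, Adgrl4 and Kcnk12 had 0 UMIs with DMSO, while Jchain had 3 against 44912 and Car1 28 against 17078. List medians were 5.27 for mast, 5.48 for maturing neutrophil, 2.82 for macrophage, -4.83 for neutrophil progenitor, -1.5 for stem and multipotent progenitor, -1.67 for monocyte and -5.23 for B lineage markers (3 measured). S phase genes lay at -2.13, G2 and M phase genes at -1.83, SREBP2 targets at 1.19, ATF4 targets at 1.44, the citric acid cycle at -0.94 and glycolysis at -0.03 (mean 0.10).

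In the ATAC libraries the authors called peaks per library: 153103 in fresh marrow (160.6 Mb, mean 1898 cut sites per kb), 90321 in DMSO (72.3 Mb, 1584), 107408 in SB204990 (91.7 Mb, 2048) and 82206 in CB-839 (70.5 Mb, 1780). Of the SB204990 peaks 74.9% overlapped a DMSO peak, and of the CB-839 peaks 92.7%, while of the DMSO peaks 91.3% overlapped an SB204990 peak and 85.0% a CB-839 peak. Depth differed, with 187856301 cut sites in 8876 cells (SB204990), 114484105 in 4478 (DMSO) and 125519144 in 3244 (CB-839). Peaks were not called again at equal depth, so these overlaps do not separate a difference in chromatin from one in depth. In regions shared with DMSO, the median log2 ratio over gene spans with SB204990 was 0.93 for macrophage, 1.32 for maturing neutrophil and -0.56 for mast markers. With peaks matched at reciprocal overlap these were 0.71, 1.11 and -0.20. Neutrophil progenitor spans gave 0.94 over merged regions but -0.14 in matched peaks, so no direction is given for them. With CB-839 the medians were -0.08 for macrophage, 1.06 for maturing neutrophil, -0.17 for mast and 0.48 for erythroid spans. The maturing neutrophil median was 0.75 in matched peaks and 0.45 in regions of like peak length, where that of SB204990 was 0.62. Immediate early gene spans lay at -0.23 with SB204990 and -0.35 with CB-839, and interferon spans at -0.07 and -0.22. For DMSO over fresh, mast spans lay at 1.53 (0.93 in matched peaks). Immediate early spans lay at 0.79 (0.55) and neutrophil progenitor spans at -1.45 (-0.18), on the same side of 0 as in RNA. Macrophage spans lay at -1.26 (-0.62) and interferon spans at -0.21 (-0.15), opposite to their RNA medians. Maturing neutrophil spans lay at -0.23 but at 0.048 in matched peaks, so they did not bear out the higher RNA median.

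**Figure D4:**
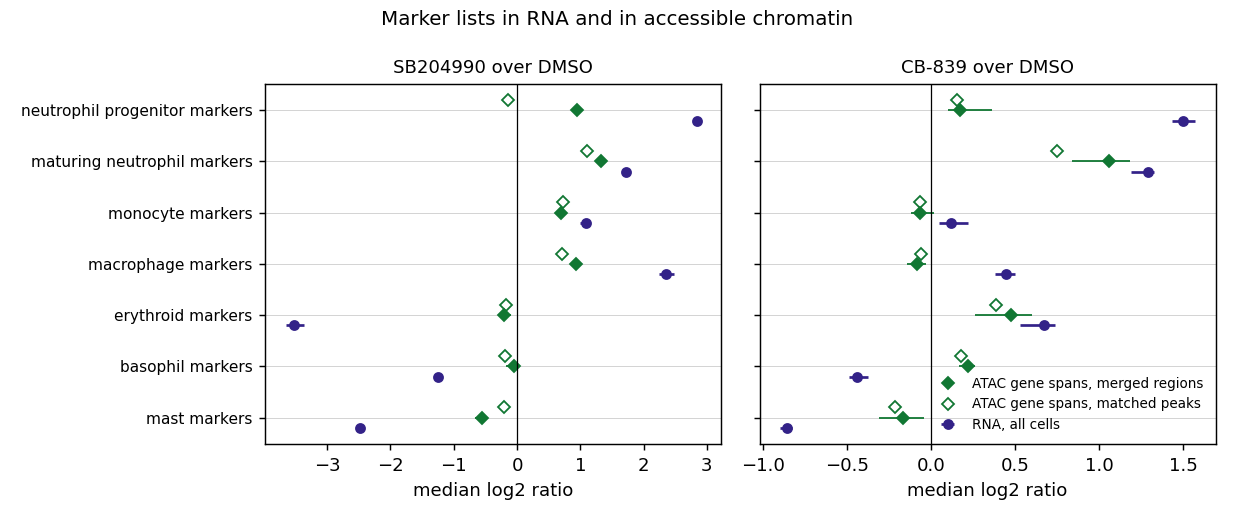
Median log2 ratio over marker lists in RNA (circles) and over ATAC gene spans in merged regions (filled diamonds) and in peaks matched at reciprocal overlap (open diamonds), SB204990 and CB-839 over DMSO; bars are 95% ranges of Poisson redraws. Macrophage markers lie at 2.36 in RNA and 0.93 in ATAC with SB204990.

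Named regions are the extremes among those shared with DMSO. With SB204990 the highest lay 90982 bp from Fshb (log2 ratio 2.37) and within BC039771 (2.25) and Mapk4 (2.24), and the lowest nearest to Chst2 (-2.56) and 2700097O09Rik (-2.55) and within Krt88 (-2.45). With CB-839 they lay nearest to Mfsd14b (1.84) and Tcp11l2 (1.69) and within Brd3 (1.59), and nearest to Ccdc42 (-1.75) and 2700097O09Rik (-1.69) and within Pla2g5 (-1.74). Motif family medians stayed between -0.14 (IRF and STAT) and 0.08 (HOX and MEIS) for SB204990 over DMSO, and between -0.23 (C/EBP) and 0.17 (ATF4 and CHOP) for CB-839, beside -0.06 and -0.09 for the CTCF control. The single motifs with the widest ratios were ZBED1 (2.52, at 0.0005% of motif counts) and Foxd3 (-1.28) for SB204990, and PAX7 (2.47) and ZNF740 (-1.5) for CB-839. PAX7 and PAX3 had the same share in DMSO (0.00192%) and in SB204990 (0.00185%), but 0.01065% and 0.00253% in CB-839. The motif tables are per library, and single-motif ratios are not read as differences between cultures. For DMSO over fresh, IRF and STAT motifs lay at 0.87 and PU.1 and SPI motifs at 0.58, and per count in peaks at 0.55 and 0.26.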

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

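Of the tests weighed here, only the class-weighting test of the immediate early and interferon medians was chosen before its result was seen; the others were chosen after.

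In the SB204990 culture the mast-like share was lower and the macrophage-like share higher than with DMSO. Cells lost to the filter do not account for the mast-like share, which without any filter still differed by -41.49 percentage points. For the macrophage-like share new clusters without the filter gave 13.09 points, between the bounds of 5 and 20, but with all 126 removed DMSO barcodes and none of the 394 removed SB204990 barcodes counted as macrophage-like it would still be 19.1 points higher, so lost cells are argued against as its whole cause while its size depends on the clustering. An error of the RNA library alone is argued against by the separate ATAC library, where macrophage gene spans exceeded mast gene spans by 1.485 (log2), and by 0.915 in peaks matched at reciprocal overlap. With 1 library per treatment, a difference between single cultures stays open, and an effect of SB204990 on which cells grow is a hypothesis.

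Immediate early and interferon medians were lower in both inhibitor libraries than in DMSO. A shift in the shares of the weighted classes as the whole cause is argued against: with DMSO class weights the 4 medians ran from -1.51 to -0.989, past the bound of -0.5 set beforehand. The weights leave out classes and clusters with under 20 cells in either library, so they covered 79.5% of SB204990 and 86.2% of DMSO cells, and 95.5% and 98.6% for CB-839 over DMSO. Mast-like cells were weighted as 1 unit, so a shift among their clusters was not removed: cluster 13 held 717 DMSO, 8 SB204990 and 97 CB-839 cells. In clusters 12 and 15 the immediate early medians were -1.49 and -0.84 with SB204990 and -1.59 and -1.16 with CB-839. The interferon medians there were -1.52 and -1.42 with SB204990 and -0.94 and -0.45 with CB-839, the last short of -0.5. The inhibitor libraries lay close to each other for immediate early genes (-0.053), which a peculiar DMSO library could give as well as a shared effect of SB204990 and CB-839. The series holds no second DMSO RNA library to decide between them.

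Lyz2, Ngp and Prg2 UMIs in mast-like cells of the SB204990 library may be free RNA from macrophage-like, neutrophil-like and eosinophil-like cells. Rates per droplet were estimated from the share of cells with a UMI, which leaves out how many UMIs a cell held. In mast-like, basophil-like and erythroid-like cells these rates differed 1.4-fold for Ngp, 1.63-fold for Prg2 and 2.05-fold for Lyz2. The bounds were within 2-fold if free RNA and over 4-fold if not. Mean UMIs per cell, in the same order of classes, were 1.04, 1.3 and 1.23 for Ngp and 0.43, 0.54 and 0.89 for Prg2. For Lyz2 they were 0.57, 3.62 and 28.73, past the 4-fold bound. These bounds were first written before the values were seen, but on CPM, where the ratios were 3.38 for Ngp, 1.95 for Prg2 and 12.61 for Lyz2. On that first scale Prg2 would have met the free RNA bound, Ngp would have been undecided and Lyz2 would have counted against free RNA. The move to droplets was made after seeing this, because free RNA adds UMIs per droplet whatever the depth of the cell. Median depth ran from 6369.5 UMIs in mast-like to 38783 in erythroid-like cells. Lyz2 stays open, since its rate and its mean UMIs per cell fall on different sides of the 4-fold bound.

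More SB204990 barcodes exceeded 10% mitochondrial UMIs, 6.37% (5.66 to 7.13%) against 2.02% (1.54 to 2.61%) with DMSO, a difference in barcodes the comparisons leave out. Tcrg-C1, left out by the rule for named genes, stood at 57.9 CPM with CB-839 and 33.8 with DMSO, while Ighv1-23 (22.5 against 42.2) and Trdv4 (18.6 against 25.8), left out by the same rule, were lower with CB-839. The remaining results stood out because list medians moved in opposite directions in mast-like and basophil-like cells, a difference that was not tested. For SB204990 over DMSO, SREBP2 targets differed by 0.494 (0.272 in mast-like and -0.222 in basophil-like cells) and glycolysis by 0.753 (0.497 and -0.256). G2 and M phase genes differed by 0.911 (0.478 and -0.433, with 3 members measured in basophil-like cells) and lineage transcription factors by -0.481 (-0.268 and 0.213). For CB-839 over DMSO, LXR targets differed by -0.587 (-0.293 and 0.294) and red cell genes by 1.372 (0.444 and -0.928), though Hbb-bt UMIs were in 6.39% of CB-839 and 5.14% of DMSO mast-like cells and are not read as a change of those cells.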

How the results depend on the processing

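Chosen only after results were seen were the settings with every cluster named after its best list, at least 5000 UMIs per cell, without the highest doublet scores and with ATAC regions of like peak length. All 336 alternative values of genes named over all cells kept their sign, while 11 of these genes with 0 UMIs in 1 library have none. The genes were picked for the widest ratios, so their kept signs say little about other genes. No alternatives were run for genes named within classes. Of 203 values for class share differences 185 kept their sign and 10 reversed a called value. For list medians these counts were 575 and 15 of 612, and for ATAC 605 and 14 of 656. No paired analysis was possible because each group has 1 library and the groups share only 1 replicate number. Class weighting gave no value for DMSO over fresh, where it covered 2.6% of DMSO cells; that limit was set after seeing this coverage. Thinning left out 24 fresh, 173 DMSO, 198 SB204990 and 347 CB-839 cells with under 2000 UMIs. Except where stated, the cause of a move was not tested.

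Class shares, in percentage points. Marker score per cell: SB204990 minus DMSO basophil-like 4.81 (main -2.24), macrophage-like 16.52, mast-like -33.15, maturing neutrophil-like 2.96; CB-839 minus DMSO macrophage-like 1.44, mast-like -9.31; DMSO minus fresh neutrophil progenitor-like -21.82; SB204990 minus CB-839 eosinophil-like -0.06. No filter: SB204990 minus DMSO macrophage-like 13.09, mast-like -41.49, maturing neutrophil-like 2.28, CB-839 mast-like -9.73, DMSO minus fresh basophil-like -3.97 and neutrophil progenitor-like -64.29. At least 1000 genes and at most 5% mitochondrial UMIs: SB204990 macrophage-like 34.11, mast-like -47.72, maturing neutrophil-like 5.35, CB-839 macrophage-like 6.79, mast-like -21.28, DMSO minus fresh basophil-like -0.91, megakaryocyte-like 0.21. The 6 doublets kept: SB204990 macrophage-like 30.95, mast-like -45.81, maturing neutrophil-like -1.86 (main 8.24), CB-839 mast-like -15.0, SB204990 minus CB-839 maturing neutrophil-like -2.53. At least 5000 UMIs: SB204990 macrophage-like 29.13, CB-839 macrophage-like 7.07, mast-like -22.55. Every cluster named: SB204990 minus DMSO basophil-like 14.11, macrophage-like 30.62, mast-like -48.94, maturing neutrophil-like 0.10, SB204990 minus CB-839 basophil-like 6.62 (main -7.73), maturing neutrophil-like -0.91. By construction these moves come from naming. Mast-like shares stayed lower and macrophage-like shares higher than DMSO in both inhibitor libraries under each of these settings. The CB-839 ATAC library did not show the latter: its macrophage gene spans had a median log2 ratio of -0.083, with 7 of 8 below 0. Main values of other reversed shares were 1.51 (eosinophil-like) and 6.44 points (maturing neutrophil-like) for SB204990 minus CB-839. For DMSO minus fresh they were 8.94 (basophil-like) and -14.63 points (megakaryocyte-like).

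List medians over DMSO, SB204990 then CB-839. Pseudocount 10 CPM: interferon -0.98 and -0.88, immediate early -0.99 and -1.13, SB204990 macrophage 1.80, mast -2.02. No low filter: interferon -0.97 and -1.26, mast -2.00 and -0.69, SB204990 eosinophil -0.06 (main 0.514), and -0.22 over CB-839 (main 0.949). TMM: interferon -1.18 and -0.95, mast -2.36 and -0.77. DMSO class weights: interferon -1.51 and -0.99, immediate early -1.47 and -1.17, macrophage 0.20 and -0.043, mast -0.58 and -0.22, eosinophil -0.084 and -0.28; SB204990 integrins -0.10, monocyte -0.55, dendritic -1.60, megakaryocyte -0.27; CB-839 red cell genes -0.21, erythroid -0.005. With CB-839 weights, SB204990 over CB-839: interferon -0.31 (main 0.295), inflammatory 0.15 (main -0.572), monocyte -0.40 (main 0.651). This setting holds class shares fixed by construction. Thinned cells: interferon -1.05, immediate early -1.42, mast -2.16 for SB204990, mast -0.58 for CB-839, eosinophil DMSO over fresh -0.19 (main 1.436).

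ATAC. Overlap with DMSO peaks of SB204990 and CB-839 peaks: 64.01% and 84.17% at reciprocal overlap, 76.29% and 94.93% for peaks with more counts. Gene spans in matched peaks: SB204990 over DMSO neutrophil progenitor -0.14, macrophage 0.71, mast -0.20; DMSO over fresh maturing neutrophil 0.048, eosinophil 0.67, B lineage 0.34; SB204990 over CB-839 neutrophil progenitor -0.22. Like peak length: SB204990 over DMSO neutrophil progenitor -0.17, macrophage 0.42; DMSO over fresh maturing neutrophil 0.37, monocyte 0.47, eosinophil 1.57, B lineage 0.23; SB204990 over CB-839 neutrophil progenitor -0.18. Main DMSO over fresh gene span medians, reversed above, were -0.232 for maturing neutrophil, -0.625 for monocyte, -0.598 for eosinophil and -1.005 for B lineage markers. The main SB204990 over CB-839 neutrophil progenitor median was 0.505. Motifs per count in peaks: SB204990 PU.1 and SPI 0.10, CB-839 C/EBP -0.21. Reversed for DMSO over fresh were GATA -0.085 (main 0.234), MITF and TFE -0.10 (main 0.22) and NFE2, MAF and BACH -0.10 (main 0.22).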

Other observations

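All values in this part were chosen after they were seen, and no explanation was tested for them.

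Erythroid-like cells carried different amounts of haemoglobin RNA: Hbb-bs stood at 335 CPM in fresh marrow (104 cells), 68438 with DMSO (43 cells), 7792 with SB204990 (44 cells) and 57464 with CB-839 (82 cells). Hba-a1 stood at 198, 12091, 489 and 10230 CPM and Alas2 at 4.88, 547, 27.6 and 466 CPM in the same order. Klf1 (244, 306, 158 and 323 CPM) and Gata1 (184, 270, 249 and 224 CPM) differed less. The cultures have under 100 such cells each, and the fresh ones are those left after lineage depletion. Lyz2 stood at 727 CPM in the SB204990 erythroid-like cells, with UMIs in 23 of 44, against 2.23 CPM with DMSO. Doublets were in effect not removed. Cluster 23, led by Ankrd37, Adm, Hilpda, Ddit3 and Bnip3, held 186 SB204990, 7 CB-839, 1 DMSO and 0 fresh cells.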
